A study of Mus musculus with 12 samples.

How the data were processed

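Gene expression was measured in skin biopsies of female Balb/c mice on Affymetrix Mouse Gene 1.0 arrays. The labels put the 12 samples into 4 groups of 3: skin of untreated mice, and skin taken 1.5 h, 6 h or 24 h after RNAdjuvant was injected into the dermis. The labels number the samples of each group from 1 to 3 and call them biological replicates. The dose is 25 mg as labelled, a unit that was not checked here. Per the labels' protocols, the tissue was kept in RNAlater, RNA was purified on columns with DNase, 50 ng was amplified, and 2.0 µg of cDNA was labelled with biotin. Untreated mice were the only controls, and no injection of carrier alone was analysed here. Clock time of collection, body site of the biopsy and array batch are not given in the sources used here.

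The deposited values are log2 intensities made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. The table holds 35556 probe sets on 12 arrays, with values from 0.65 to 14.11 and array medians from 5.53 to 5.76. It carries no detection p-values, so a low value was not called absent. The platform annotation listed 23410 of the probe sets. Of these, 21789 had 1 gene symbol and 1621 had several. The other 12146 were not listed and stayed unnamed. No gene was named from a probe set with several symbols, which leaves out Isg15. Of the gene IDs, 21698 were found in the RefSeq table, through which 0 symbols changed, and no coordinates were used. Where a gene had several probe sets (999 genes), the one with the highest mean over the 12 arrays was kept, which left 19938 genes.

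All groups were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 8 residual and 5.24 prior degrees of freedom. Each time was compared with the untreated group and with each other time, which makes 6 comparisons. A moderated F test over the 3 comparisons with untreated skin asked which genes changed at any time. P-values were adjusted by the Benjamini-Hochberg method over all 19938 genes within a comparison, and an adjusted p under 0.05 counted as a change. A log2 change is the treated mean minus the untreated mean, or the later time minus the earlier one. Tests are two-sided. Values are given as mean ± SD of 3 arrays, and their number limits the precision. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so single genes were tested in the limma model alone.

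Of 42 gene lists for pathways and cell types, 41 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01. In all, 761 of 849 list entries were measured. Camera asks whether a list moved more than other genes. It was repeated with the correlation estimated from the data, and fry was run beside it, which asks whether a list's genes move on balance one way. P-values of lists were adjusted over the lists within a comparison. For each list the members that rose or fell are counted with p adjusted over all genes and again adjusted over the list alone.

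The groups, the tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule takes the 10 largest rises and 6 largest falls in each comparison with untreated skin among changed genes whose groups do not overlap, skipping predicted genes. It adds up to 4 members of each list described: the 3 with the largest change, and the largest that passed the other way. Ifnb1, Isg15, Cxcl10, Il6, Tnf, Ccl2, Tlr7, Ddx58 and Ifih1 are named at each time where measured. Between times it takes 5 rises and 5 falls. Glycam1, Myl2, Krt18, Csn3, Wfdc18, Wfdc2, Cited1, Elf5, Krt8, Ncr1, Mir143, Fmnl2 and Rufy3 fall outside the rule and were chosen after their values were seen. So was the mean of Krt18, Krt19, Csn3 and Wfdc18 used as a glandular score.

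The steps were tested on simulated data made like the 6 h comparison, with 200 of 19938 genes changed, in 20 simulations. Of genes changed by 0.5, 1 and 2 log2 units, 26.8%, 94.4% and 100% were called, and a mean of 8 unchanged genes was called. With nothing changed, simulated as for the 24 h comparison, a mean of 0.05 genes was called.

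The alternatives tried were the replicate number as a block, leaving out each library in turn, other variance models and array weights, filters on dim probe sets, a floor, 3 further scalings between arrays, other rules for genes with several probe sets, no moderation of the variance, stricter thresholds and fits of only the groups compared. An alternative without the libraries high in Glycam1, a lymph node vessel gene, and another with a score of glandular epithelium as a covariate were added after the data were seen. Results are set out for a closer look where a list's difference between times held with an estimated correlation, or where a gene changed in opposite directions at different times. Single outlying samples were not tested for in groups of 3, and no data outside the comparisons were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.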

Results

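Expression was measured on 12 arrays of mouse skin, 3 from untreated mice and 3 each taken 1.5 h, 6 h and 24 h after an injection of RNAdjuvant into the dermis. RNAdjuvant is a vaccine adjuvant made of a non-coding RNA bound to a cationic peptide, and such RNA is known to trigger the innate receptors of foreign RNA. The comparisons ask which genes were higher or lower in the skin at each time. Array medians lay between 5.53 and 5.76 on the log2 scale. Over all probe sets, arrays of the same group correlated at r = 0.98 to 0.987 (12 pairs) and arrays of different groups at r = 0.961 to 0.986 (54 pairs).

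Among genes named by the fixed rule, the largest rise over untreated skin was that of Ifnb1, which encodes interferon beta, at 1.5 h, of the antiviral gene Rsad2 at 6 h and of the acute phase gene Saa3 at 24 h. The granzyme genes Gzmb and Gzma, whose products kill target cells, were among the largest rises at 24 h. At any of the 3 times, 2274 of 19938 genes changed (11.4%, moderated F test, against 6232 at an unadjusted p under 0.05). That count was 1370 without untreated replicate 3, 1320 without 1.5 h replicate 2 and 1189 without 6 h replicate 2.

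**Figure D1:**
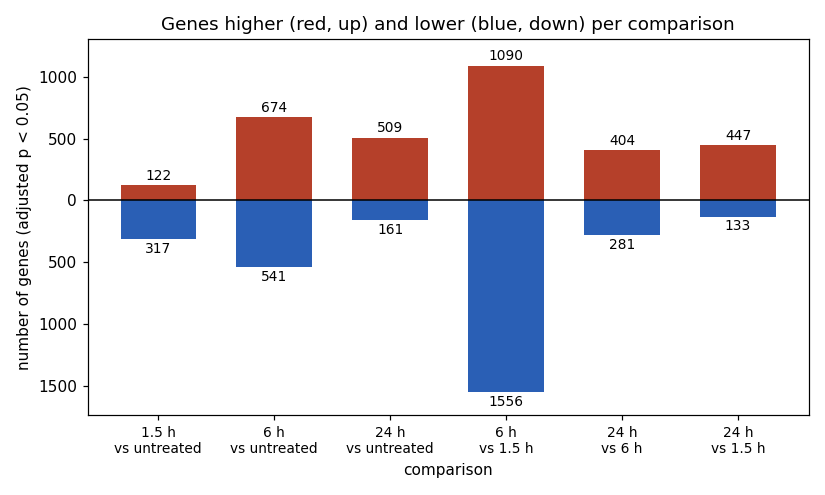
Bars give the number of genes with an adjusted p under 0.05 in each of the 6 comparisons (horizontal axis), higher ones above 0 in red and lower ones below 0 in blue. Higher calls outnumbered lower ones at 24 h (509 against 161) and lower ones outnumbered higher ones at 1.5 h (317 against 122), a split that other scalings of the arrays moved.

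At 1.5 h several interferon, chemokine and cytokine genes rose in the skin and several sebaceous gland genes fell. Ifnb1 (probe set 10514285) rose 20.3-fold, from 3.42 ± 0.15 to 7.77 ± 0.39 (SD, n = 3, adjusted p = 1.37e-08), and the interferon alpha gene Ifna4 rose 4.28-fold (adjusted p = 0.00535). Cxcl10 (probe set 10531415), a chemokine that draws activated lymphocytes, rose 9.81-fold from 6.11 ± 0.17 to 9.4 ± 0.49 (SD, n = 3). Ccl3, Ccl2 and Ccl7, which draw monocytes, rose 7.65-, 7.39- and 5.38-fold. Ptx3, a soluble pattern recognition protein, rose 9.52-fold, and Il6, the fever and acute phase cytokine, rose 6.73-fold. Ifit1, an interferon-induced inhibitor of viral RNA translation, rose 6.21-fold. Lcn2, which binds bacterial siderophores, rose 6.69-fold, Krt19, a keratin of simple and glandular epithelium, rose 5.75-fold, and the cytokine gene Tnf rose 1.95-fold. The call of Lcn2 was lost without untreated replicate 2 or 1.5 h replicate 1 (adjusted p = 0.0792 and 0.0553), and that of Tnf without untreated replicate 2 or 3 or 1.5 h replicate 2 (adjusted p = 0.0816, 0.083 and 0.0506). The call of Krt19 was lost without any of the 6 libraries compared or without 24 h replicate 1 (adjusted p up to 0.138, without 1.5 h replicate 1).

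Of the 16 measured neutrophil and monocyte chemokines, 7 rose and 9 did not pass (10 rose adjusted over the list alone). This list had a median change of 1 log2 unit (camera adjusted p = 1.96e-11), and of the 22 lists camera called at 1.5 h it was the only one called with an estimated correlation (adjusted p = 0.0302, fry called 5 lists). Of 15 interferon genes, Ifnb1 and Ifna4 rose and 13 did not pass, with 2 also adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.371 with an estimated correlation, and 0.127 by camera on ranks). Of 47 type I interferon-stimulated genes, 5 rose and 42 did not pass, led by Ifit1, Rsad2 (4.05-fold) and Mx2 (3.27-fold), and 12 rose and 1 fell adjusted over the list alone. That list was called by camera (adjusted p = 1.14e-05, adjusted p = 0.613 with an estimated correlation), but not without 1.5 h replicate 1 (adjusted p = 0.176), where the lymph node vessel gene Glycam1 measured 11.38, nor with a score of glandular genes as a covariate (adjusted p = 0.564). That score separates these groups, so the fit with it would remove a response as well and cannot decide this. Of 26 nucleic acid sensors and their adaptors, Dhx58, a relative of RIG-I, rose 2.15-fold and 25 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.00248, adjusted p = 0.47 with an estimated correlation). The call of Dhx58 was lost without untreated replicate 2 (adjusted p = 0.0842). The RNA receptor genes Tlr7, Ddx58 (RIG-I) and Ifih1 (MDA5) had log2 changes of 0.35, 0.06 and 0.25 (adjusted p = 0.462, 0.889 and 0.265).

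Immediate early genes, which answer within minutes to hours of a stimulus, rose in 4 of 27 cases and 23 did not pass, led by Fosb (2.81-fold) and Fosl1 (2.4-fold), with 10 adjusted over the list alone. Camera called that list (adjusted p = 1.61e-06, adjusted p = 0.411 with an estimated correlation). Of 25 inflammatory cytokines, Il6 and Tnf rose and 23 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.00509, adjusted p = 0.497 with an estimated correlation). Bcl3, an NF-kB cofactor, rose 2.46-fold and was the member called among 20 NF-kB target and feedback genes, also adjusted over the list alone (camera adjusted p = 0.000316, adjusted p = 0.497 with an estimated correlation). Without untreated replicate 2 the call of Bcl3 was lost (adjusted p = 0.0557). Lcn2 and Saa3 (2.77-fold) rose among 16 acute phase and complement genes and 14 did not pass, with 3 adjusted over the list alone (camera adjusted p = 0.00509, adjusted p = 0.466 with an estimated correlation, and 0.0697 without 1.5 h replicate 1 at the preset one). Mt2, a metallothionein, rose 1.81-fold and was the member called among 14 glucocorticoid-responsive genes, 4 of which rose adjusted over the list alone (camera adjusted p = 0.0152, adjusted p = 0.466 with an estimated correlation, and 0.0681 without 1.5 h replicate 3 at the preset one). Irf1 (1.84-fold), a transcription factor of the interferon response, rose with Irgm1 (1.75-fold) among 16 interferon-inducible GTPases and gamma-interferon targets, a list that camera did not call (adjusted p = 0.848). The call of Irgm1 was lost without each untreated library and without 1.5 h replicate 1 or 2 (adjusted p up to 0.107, without untreated replicate 3).

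Neutrophil markers rose in 4 of 19 cases and 15 did not pass, with 10 adjusted over the list alone. S100a9, a calcium-binding protein of neutrophils, rose 5.04-fold and Clec4e, a receptor of damaged cells and mycobacteria, rose 3.14-fold (camera adjusted p = 2.11e-07 for the list, adjusted p = 0.371 with an estimated correlation, and 0.055 by fry). The median of the list lay 1.11 above untreated skin in 1.5 h replicate 1, the library high in Glycam1, and 0.25 and 0.34 above it in replicates 2 and 3. The call of S100a9 was lost without untreated replicate 2 or 3 (adjusted p = 0.0718 and 0.0763). Camera also called 13 B and plasma cell markers, of which 0 passed in limma and 0 adjusted over the list alone, against 3 at an unadjusted p under 0.05 (camera adjusted p = 0.00509, adjusted p = 0.613 with an estimated correlation), but not without 1.5 h replicate 1 (adjusted p = 0.692). In that library Glycam1, a gene chosen after its values were seen, measured 11.38 and the B cell receptor gene Cd79b 7.8. In 6 h replicate 1 they measured 10.88 and 7.29, and Glycam1 lay between 3.87 and 4.46 in the other 10 libraries. Camera called 24 mitochondrial respiration genes (adjusted p = 3.77e-08, adjusted p = 0.483 with an estimated correlation) and 25 skeletal muscle genes (adjusted p = 0.000205, adjusted p = 0.634 with an estimated correlation) upward. Of the former Sdhd, a subunit of succinate dehydrogenase, rose 1.53-fold and 23 did not pass, and of the latter 0 passed in limma (4 at an unadjusted p under 0.05), with the same counts adjusted over the lists alone. Without untreated replicate 2 or 3 or 1.5 h replicate 1 or 2 the call of Sdhd was lost (adjusted p up to 0.127, without untreated replicate 2). Myl2, a myosin light chain of slow and heart muscle also chosen after its values were seen, measured 10.56 and 10.43 in 1.5 h replicates 1 and 2, 10.57 and 9.33 in 24 h replicates 1 and 3, and 6.88 or less in the other 8 libraries.

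**Figure D2:**
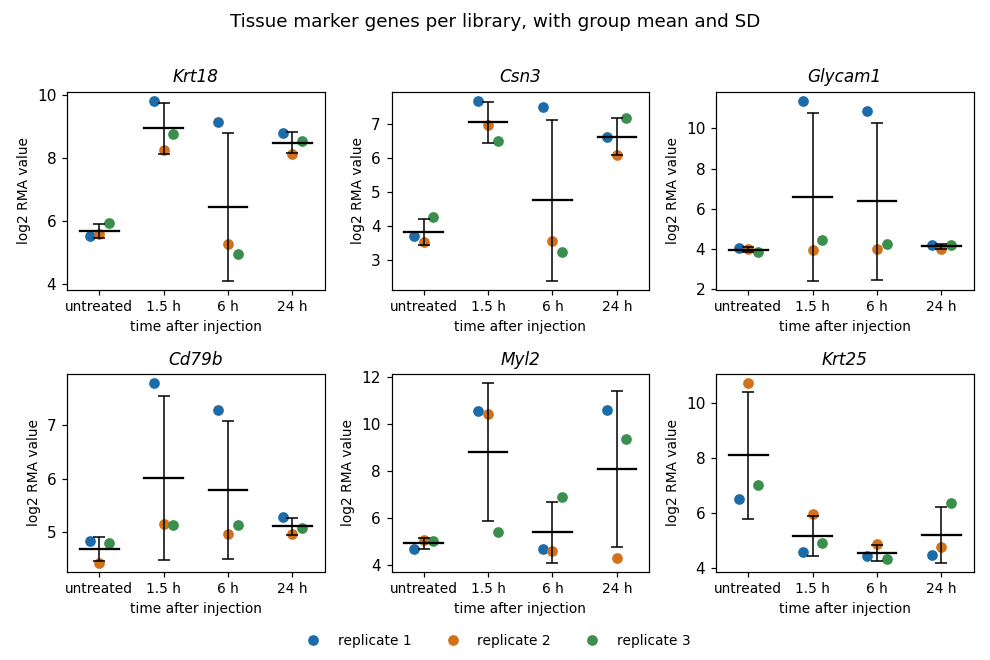
Log2 RMA values (vertical axes) of 6 tissue marker genes in the 12 libraries by group (horizontal axes), with replicates in 3 colours and the mean and SD of each group in black. Krt18 and Csn3 lie low in all untreated libraries and in 6 h replicates 2 and 3, Glycam1 stands at 11.38 and 10.88 in 2 libraries, and Krt25 reaches 10.74 in untreated replicate 2.

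Sebaceous gland genes, of which 14 were measured, fell in 7 cases and rose in 1, and 6 did not pass (11 fell and 1 rose adjusted over the list alone). The cytochrome P450 gene Cyp2g1 fell by 1.71 on the log2 scale, from 12.2 ± 0.01 to 10.48 ± 0.28 (SD, n = 3, adjusted p = 3.02e-05), and Awat2, an enzyme of wax ester synthesis, fell by 1.48 (adjusted p = 0.0855 without untreated replicate 3). Krt7, a keratin of ducts and glands, rose 2.9-fold. The list had a median of -1.02 (camera adjusted p = 2.09e-09, adjusted p = 0.371 with an estimated correlation). Per library, its median against untreated skin was -0.61, -1.5 and -0.93 in 1.5 h replicates 1 to 3. It was -0.49, -0.17 and -0.28 at 6 h, and -0.53, -0.35 and -1.04 at 24 h. The tissue content of the biopsies differed as well, and its part in this fall was not tested. Elovl6, which lengthens fatty acids, fell by 1.25 on the log2 scale, Hsd3b6, a steroid dehydrogenase, by 1.71, and the carnosine synthase gene Carns1 by 1.62. The microRNA genes Mir15a and Mir99a fell by 2.04 and 1.82, and Hamp, which encodes the iron hormone hepcidin, fell by 2.01. The calls of Hamp and Mir99a were lost without each of 4 and 5 libraries (highest adjusted p = 0.105 and 0.141, without untreated replicates 3 and 2). Genes of glandular epithelium, chosen after their values were seen, moved with the group in the other direction: the mean of Krt18, Krt19, Csn3 and Wfdc18 was 5.29 to 5.66 in untreated skin and 7.68 to 8.95 at 1.5 h.

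A few smooth muscle and pigment cell genes fell as well. Of 13 pericyte and smooth muscle markers, the myosin genes Myh11 and Myl9 fell by 1.48 and 0.89 and 11 did not pass (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.411 with an estimated correlation). Dct and Pmel, genes of pigment synthesis, fell by 1.22 and 0.79 among 8 melanocyte markers and 6 did not pass (4 fell adjusted over the list alone, camera adjusted p = 4.07e-06, adjusted p = 0.371 with an estimated correlation). The calls of Myl9 and Dct were lost without 4 and 3 libraries (highest adjusted p = 0.107 without untreated replicate 3, and 0.0718 without untreated replicate 2), and that of Pmel without untreated replicate 2 (adjusted p = 0.0523). Of 30 hair follicle genes, 1 fell and 29 did not pass (5 fell adjusted over the list alone), with a median of -0.71 (camera adjusted p = 3.48e-07, adjusted p = 0.497 with an estimated correlation). Krt25, a keratin of the inner root sheath, differed by -2.94 (adjusted p = 0.0918). Its untreated values were 6.51, 10.74 and 7.03.

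In all, 439 genes changed at 1.5 h, 122 higher and 317 lower (limma, 3490 at an unadjusted p under 0.05), and 112 of them by at least 2-fold. The 3 treated values lay outside the range of the 3 untreated ones for all 439, against 25.1% of all genes and 10% by chance. Genes were called on these same values, so that adds no support to the calls. The count was 280, 97 and 106 without untreated replicates 1, 2 and 3, 182 and 126 without 1.5 h replicates 1 and 2, and 55 with the glandular score in the model. That score separates these groups. Of 46 named genes called at 1.5 h, 34 lost their call without moderation of the variance, among them Il6, Rsad2 and Carns1, and 26 with values raised to a floor. Camera called 16 of 41 lists upward and 6 downward, against up to 20 lists in other splits of these samples. Higher calls made up 27.8%, and 56.9%, 43.2% or 34.7% with arrays centred on their medians, quantile normalized or after cyclic loess.

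At 6 h antiviral genes were among the largest rises, and several clock and cell division genes fell. Rsad2 (probe set 10399710), an interferon-induced inhibitor of virus replication, rose 67.3-fold from 5.27 ± 0.21 to 11.34 ± 0.14 (SD, n = 3, adjusted p = 7.69e-09), and Cxcl10 rose 61-fold. The antiviral genes Mx2, Ifit1, Ifit2 and Mx1 rose 42.7-, 34.9-, 32.3- and 30.3-fold, and the nucleotide kinase gene Cmpk2 rose 30.6-fold. Saa3 rose 36.7-fold, Ccl3 29-fold, and Ch25h, which makes 25-hydroxycholesterol, 27.4-fold. Ifnb1 stood at 5.91 ± 0.04 (SD, n = 3), 5.6-fold above untreated skin (adjusted p = 2.82e-07). Il6, Tnf and Ccl2 rose 12.3-, 3.87- and 23.5-fold.

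All 47 measured type I interferon-stimulated genes rose, by a median of 2.84 log2 units, and 47 also adjusted over the list alone (camera adjusted p = 8.38e-98, adjusted p = 0.0159 with an estimated correlation). Interferon-inducible GTPases and gamma-interferon targets rose in 14 of 16 cases and 2 did not pass, with 14 adjusted over the list alone (adjusted p = 2.46e-29 and, with an estimated correlation, 0.0159). Gbp5, Iigp1 and Irgm1, GTPases that act against intracellular microbes, rose 16.1-, 11.2- and 10.2-fold. Of 26 nucleic acid sensors and adaptors, 16 rose and 10 did not pass (17 rose and 1 fell adjusted over the list alone, adjusted p = 5.92e-17 and, with an estimated correlation, 0.0195). Dhx58 rose 11.6-fold, Irf7, the master regulator of interferon alpha genes, 9.99-fold, Ifih1 8.5-fold and Ddx58 6.75-fold, whereas Tlr7 had a log2 change of 0.48 (adjusted p = 0.242). Among the interferon genes 1 of 15, Ifnb1, rose and 14 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.0706 with an estimated correlation), and Ifng measured a log2 change of 0.51 (adjusted p = 0.0869).

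Genes of antigen presentation through MHC class I rose in 14 of 16 cases and 2 did not pass, with 15 adjusted over the list alone (camera adjusted p = 2.33e-20 and, with an estimated correlation, 0.0195). H2-T24, the immunoproteasome subunit Psmb10 and the peptide transporter Tap1 rose 4.38-, 3.45- and 2.84-fold. Costimulation and maturation genes rose in 5 of 17 cases and 12 did not pass, with 5 adjusted over the list alone, led by Tnfsf10 (TRAIL, 8.55-fold), Cd274 (PD-L1, 8.13-fold) and Cd40 (6.94-fold). Lytic cell death genes rose in 6 of 13 cases and 7 did not pass, with 9 adjusted over the list alone, led by Mlkl, the executor of necroptosis (7.97-fold), Casp4 (3.98-fold) and Gsdmd (2.07-fold). Camera called both (adjusted p = 1.37e-09 and 1.07e-08), also with an estimated correlation (adjusted p = 0.0159 and 0.0195).

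Chemokines of both lists rose. Of the neutrophil and monocyte chemokines 7 of 16 rose and 9 did not pass (11 rose and 1 fell adjusted over the list alone), with Ccl12 up 26-fold, and of the lymphocyte and dendritic cell chemokines 6 of 14 rose and 8 did not pass (9 and 1), with Cxcl11 and Cxcl9 up 27.4- and 18.6-fold. Both lists were called by camera (adjusted p = 2.92e-11 and 5.49e-09) and with an estimated correlation (adjusted p = 0.0159 and 0.0319). Inflammatory cytokines rose in 10 of 25 cases and 15 did not pass (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.02e-06, adjusted p = 0.108 with an estimated correlation), with Il10 and Il15 up 5.33- and 4.32-fold. NF-kB target and feedback genes rose in 13 of 20 cases and 7 did not pass (16 adjusted over the list alone, camera adjusted p = 1.27e-14, adjusted p = 0.0615 with an estimated correlation), led by Ptgs2, the inducible cyclooxygenase (3.88-fold), Bcl3 (3.61-fold) and Tnfaip3, a brake on NF-kB (2.89-fold). Feedback inhibitors of cytokine signalling rose in 5 of 15 cases and 10 did not pass (6 adjusted over the list alone, camera adjusted p = 0.000331 and, with an estimated correlation, 0.0319), led by Il10ra (3.56-fold), Il18bp (2.78-fold) and Socs3 (2.32-fold). Acute phase and complement genes rose in 4 of 16 cases and 12 did not pass (10 adjusted over the list alone), among them Cfb, complement factor B (3.85-fold), and adhesion genes rose in 4 of 11 and 7 did not pass (6 adjusted over the list alone), led by Vcam1 (2.78-fold) and Icam1 (2.72-fold). Camera called both (adjusted p = 1.37e-09 and 4.76e-06), also with an estimated correlation (adjusted p = 0.0319 and 0.05, the latter under the threshold before rounding).

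**Figure D3:**
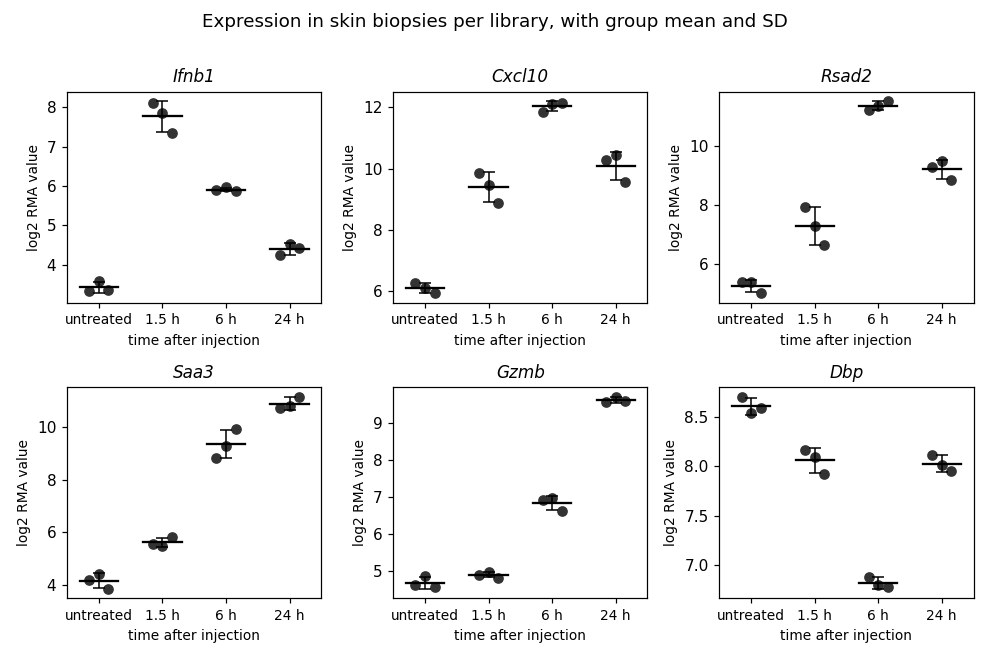
Log2 RMA values (vertical axes) of Ifnb1, Cxcl10, Rsad2, Saa3, Gzmb and Dbp in the 12 libraries by group (horizontal axes), with 3 points per group and the group mean and SD in black. Ifnb1 is highest at 1.5 h (7.77), Cxcl10 and Rsad2 at 6 h (12.04 and 11.34), Saa3 and Gzmb at 24 h (10.9 and 9.62), and Dbp is lowest at 6 h (6.82).

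Circadian clock genes fell in 8 of 17 cases and rose in 2, and 7 did not pass (10 fell and 2 rose adjusted over the list alone, camera adjusted p = 3.91e-05 and, with an estimated correlation, 0.0492). Nr1d1, the clock repressor REV-ERB alpha, fell by 2.43 on the log2 scale from 10.49 ± 0.19 to 8.06 ± 0.19 (SD, n = 3, adjusted p = 7.24e-05), the clock output gene Dbp by 1.8 (adjusted p = 8.44e-08) and Nr1d2 by 1.15, while the Dbp antagonist Nfil3 rose 2.04-fold. Cell division genes fell in 10 of 23 cases and 13 did not pass (14 adjusted over the list alone), among them Kif11, Mki67 and Top2a, which fell by 0.84, 0.76 and 0.76, and the list was called by camera (adjusted p = 1.18e-09, adjusted p = 0.114 with an estimated correlation). With the mean of its probe sets Top2a lost its call (adjusted p = 0.219). Pck1, the key enzyme of gluconeogenesis, fell by 2.23. Nnat fell by 1.81, and its call was lost without each of 8 libraries (highest adjusted p = 0.162, without 6 h replicate 2). The inner root sheath keratins Krt25 and Krt71 fell by 3.55 and 3.26, and both calls were lost without 6 h replicate 1 (adjusted p = 0.0525 and 0.0526), 2 (0.0615 and 0.0968) or 3 (0.0788 and 0.0639). Without untreated replicate 2, where Krt25 measured 10.74, the changes were -2.23 and -1.99 (adjusted p = 0.0228 and 0.0216). The hair follicle list of 30 genes, in which 2 fell and 28 did not pass (4 fell adjusted over the list alone), had a median of -0.57 (camera adjusted p = 0.000252, adjusted p = 0.623 with an estimated correlation, and 0.116 without untreated replicate 2 at the preset one).

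Among immune cell markers, the Fc receptor genes Fcgr4 and Fcgr1 rose 13.2- and 8.88-fold and Plac8 5.97-fold, 3 of the 22 monocyte and macrophage markers. In the same list Cd163, a scavenger receptor of resident macrophages, fell by 0.77, a call lost without each of 9 libraries (highest adjusted p = 0.169, without untreated replicate 1), and 18 did not pass (5 rose and 1 fell adjusted over the list alone). Camera called the list (adjusted p = 0.00131, adjusted p = 0.64 with an estimated correlation), but not without 6 h replicate 1 (adjusted p = 0.125), where Glycam1 measured 10.88, or untreated replicate 2 (adjusted p = 0.134). T and natural killer cell markers rose in 4 of 23 cases and 19 did not pass (5 adjusted over the list alone, camera adjusted p = 5.15e-07, adjusted p = 0.194 with an estimated correlation), led by Gzmb (4.42-fold), the activating receptor gene Klrk1 (3.37-fold) and Gzma (3.29-fold). The median of that list lay 0.71 above untreated skin in 6 h replicate 1, the library high in Glycam1, and 0.19 and 0.17 above it in replicates 2 and 3. In these libraries 8 genes of the T cell receptor complex had means of 6.81, 5.83 and 5.95. Neutrophil markers rose in 5 of 19 cases and 14 did not pass (7 adjusted over the list alone, camera adjusted p = 2.59e-05, adjusted p = 0.223 with an estimated correlation), led by Clec4e (4.55-fold) and Clec4d (3.12-fold). Immediate early genes rose in 5 of 27 cases and 22 did not pass (8 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.00369, adjusted p = 0.516 with an estimated correlation), led by Atf3 (4.5-fold), Zfp36 (1.93-fold) and Dusp2 (1.75-fold).

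In all, 1215 genes changed at 6 h, 674 higher and 541 lower (limma, 4616 at an unadjusted p under 0.05), and 325 by at least 2-fold. The groups did not overlap for 1211 of them, against 30.8% of all genes and 10% by chance, which again largely follows from calling genes on these values. The count was 740 and 712 without untreated replicates 1 and 3, and 732 and 757 without 6 h replicates 2 and 3. Of 79 named genes called, 10 lost their call without moderation of the variance. Camera called 18 of 41 lists upward and 5 downward, 12 of them with an estimated correlation, and fry called 19. Other splits of these samples gave up to 24 lists by camera, so its number of lists says little about the groups. Higher calls made up 55.5%, against 48.4% with arrays centred on their medians, 59.6% quantile normalized and 69.4% after cyclic loess.

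At 24 h the acute phase gene Saa3 and genes of cytotoxic and myeloid cells showed the largest rises, and the antiviral genes were still high. Saa3 (probe set 10563597) rose 108-fold from 4.14 ± 0.28 to 10.9 ± 0.23 (SD, n = 3, adjusted p = 1.97e-09). Gzmb (probe set 10420308) rose 30.6-fold from 4.68 ± 0.16 to 9.62 ± 0.08 (SD, n = 3, adjusted p = 4.11e-11) and Gzma 20.3-fold. Fcgr4 rose 25.3-fold and Ms4a4c, a membrane protein of lymphoid and myeloid cells, 22.3-fold. Ccl5, Cxcl9, Cxcl11 and Cxcl10, which draw T and natural killer cells, rose 19.7-, 19.4-, 16.6- and 15.8-fold, and Rsad2 15.1-fold. Ifnb1 was 1.97-fold above untreated skin (adjusted p = 0.00312, but 0.272 with values raised to a floor and 0.0806 with the glandular score as a covariate), Ccl2 14.9-fold, Tnf 2.27-fold and Il6 3.67-fold. The glandular score separates these groups, so the fit with it cannot tell whether the rise of Ifnb1 was a response. The call of Il6 was lost without untreated replicate 1 or 24 h replicate 2 (adjusted p = 0.0759 and 0.0708).

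All 47 type I interferon-stimulated genes were again higher than in untreated skin, by a median of 2.23 log2 units, and 47 adjusted over the list alone (camera adjusted p = 9.61e-95, adjusted p = 0.0103 with an estimated correlation), with Ifit3 up 13.3-fold. GTPases and gamma-interferon targets rose in 14 of 16 cases and 2 did not pass, and MHC class I genes likewise in 14 of 16 (14 and 16 adjusted over the list alone). Both were called with either correlation (adjusted p = 9.81e-31 and 1.71e-28, and 0.0103 for each with an estimated correlation). Gbp3 and Iigp1 rose 8.69- and 8.56-fold, and H2-T24, Psmb10 and Psmb8 4.47-, 3.23- and 3.06-fold. Sensors and adaptors rose in 12 of 26 cases and 14 did not pass (18 adjusted over the list alone, camera adjusted p = 2.53e-17 and, with an estimated correlation, 0.016). Irf7, Dhx58 and Tlr13, a receptor of bacterial RNA, rose 13.1-, 7.47- and 5.39-fold, Ifih1 and Ddx58 3.4- and 3.21-fold, and Tlr7 had a log2 change of 0.59 (adjusted p = 0.223).

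Acute phase and complement genes rose in 8 of 16 cases and 8 did not pass (11 adjusted over the list alone, camera adjusted p = 2.23e-15 and, with an estimated correlation, 0.0103), with Lcn2 up 7.99-fold and Cfb 5.33-fold. Neutrophil and monocyte chemokines rose in 9 of 16 cases and 7 did not pass (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.37e-13 and, with an estimated correlation, 0.0103), with Ccl3 and Ccl12 up 10.4- and 9.88-fold. Lytic cell death genes rose in 6 of 13 cases and 7 did not pass (9 adjusted over the list alone, camera adjusted p = 3.56e-11 and, with an estimated correlation, 0.0103), led by Mlkl (5.63-fold). Adhesion genes rose in 4 of 11 cases and 7 did not pass (6 adjusted over the list alone, camera adjusted p = 3.22e-07 and, with an estimated correlation, 0.0437), among them Vcam1 (2.15-fold). The costimulation list had 5 of 17 genes higher and 12 not passing (6 adjusted over the list alone, camera adjusted p = 0.000112, adjusted p = 0.0618 with an estimated correlation), led by Cd274 (4.78-fold). Feedback inhibitors rose in 3 of 15 cases and 12 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00777, adjusted p = 0.0896 with an estimated correlation): Il18bp, which neutralises interleukin 18 (4.35-fold), Il10ra (2.13-fold) and the checkpoint receptor gene Lag3 (1.79-fold). Lymphocyte and dendritic cell chemokines rose in 5 of 14 cases and 9 did not pass (6 adjusted over the list alone, camera adjusted p = 2.92e-06, adjusted p = 0.0739 with an estimated correlation).

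T and natural killer cell markers rose in 10 of 23 cases and 13 did not pass (11 adjusted over the list alone, camera adjusted p = 4.87e-15, adjusted p = 0.0624 with an estimated correlation), with Klrk1 up 4.41-fold beside the granzymes. Monocyte and macrophage markers rose in 9 of 22 cases and 13 did not pass (14 rose and 2 fell adjusted over the list alone, camera adjusted p = 3.75e-10, adjusted p = 0.272 with an estimated correlation), with Fcgr1 and Plac8 up 8.96- and 6.59-fold. Neutrophil markers rose in 5 of 19 cases and 14 did not pass (8 adjusted over the list alone, camera adjusted p = 1.25e-05, adjusted p = 0.242 with an estimated correlation), led by Clec4e at 10.2-fold. Inflammatory cytokines rose in 5 of 25 cases and 20 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00246, adjusted p = 0.311 with an estimated correlation), among them Il1b (2.18-fold). The mean of Krt18, Krt19, Csn3 and Wfdc18 was 7.49 to 8.17 in the 24 h libraries, above the 5.29 to 5.66 of untreated skin.

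**Figure D4:**
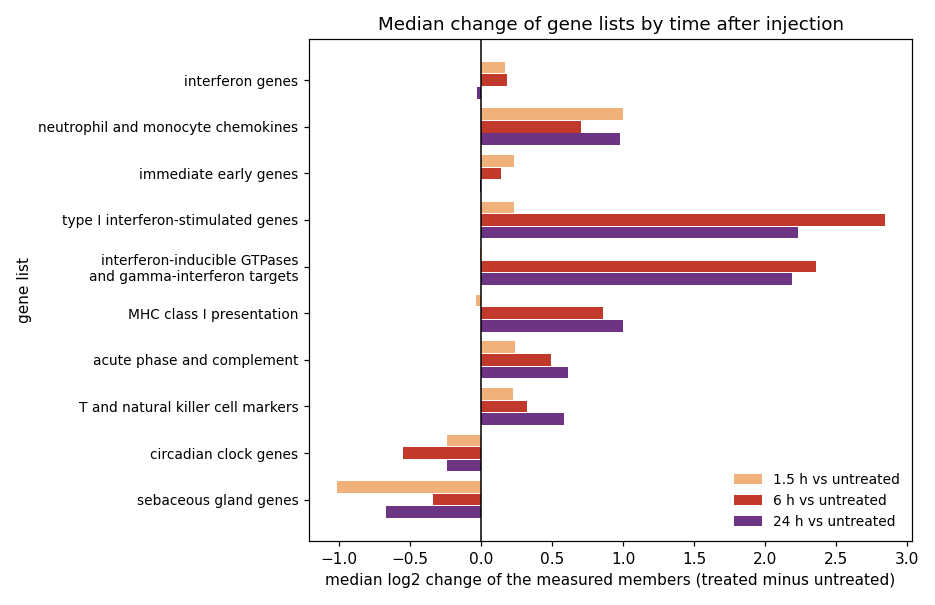
Bars give the median log2 change of the measured members of 10 gene lists (vertical axis) against untreated skin at 1.5 h, 6 h and 24 h, in 3 colours. Interferon-stimulated genes have medians of 0.23, 2.84 and 2.23 at 1.5 h, 6 h and 24 h, neutrophil and monocyte chemokines of 1, 0.7 and 0.98, and sebaceous gland genes of -1.02, -0.34 and -0.67.

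The largest falls at 24 h were smaller than the rises. Hrnr, which encodes the barrier protein hornerin, fell by 1.11 on the log2 scale from 11.06 ± 0.04 to 9.95 ± 0.1 (SD, n = 3, adjusted p = 2.51e-05). Cd209c, a C-type lectin of the DC-SIGN family, and Cyp2b19, an arachidonic acid epoxygenase of keratinocytes, fell by 1.23 each, the steroid enzyme gene Cyp17a1 by 1.21, Carns1 by 1.16 and the secretoglobin gene Scgb3a2 by 1.13. The call of Cyp2b19 was lost without untreated replicate 3 (adjusted p = 0.0517), that of Carns1 without 24 h replicate 3 or untreated replicate 2 or 3 (adjusted p = 0.0789, 0.078 and 0.066), and that of Scgb3a2 without each of 7 libraries (highest adjusted p = 0.171, without 24 h replicate 3). Of 14 sebaceous gland genes, Cyp2g1 fell by 1.02 and Krt7 rose 2.15-fold, and 12 did not pass (10 fell and 1 rose adjusted over the list alone, camera adjusted p = 4.39e-05, adjusted p = 0.291 with an estimated correlation). Krt7 lost its call without each of 5 libraries (highest adjusted p = 0.106, without untreated replicate 2). Clock genes fell in 3 of 17 cases and rose in 1, and 13 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.000573, adjusted p = 0.0896 with an estimated correlation), and the clock genes Per3 and Dbp fell by 0.71 and 0.59 log2 units.

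In all, 670 genes changed at 24 h, 509 higher and 161 lower (limma, 3407 at an unadjusted p under 0.05), and 292 by at least 2-fold. The groups did not overlap for all 670, against 23.3% of all genes and 10% by chance, which also largely follows from calling genes on these values. The count was 423 without untreated replicate 2, 440 without 24 h replicate 3 and 307 with the glandular score in the model. That score separates these groups too. Of 73 named genes called, 20 lost their call without moderation of the variance, among them Cd209c, Lcn2 and Il1b, and 19 with the glandular score. Camera called 16 of 41 lists upward and 9 downward, 8 of them with an estimated correlation, and fry called 16. Other splits of these samples gave up to 21 lists by camera.

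From 1.5 h to 6 h interferon-stimulated genes rose while Ifnb1 and several clock genes fell. Mx1, Cxcl11, Ch25h, Ifi209 and Slfn4, all known to respond to interferon, rose 22.8-, 21.9-, 19.2-, 19- and 18.2-fold. Ifnb1 fell by 1.86 on the log2 scale (adjusted p = 5.91e-06), Pck1 by 2.39, Nr1d1 by 1.95, the endothelin receptor gene Ednrb by 1.89 and Efhd1 by 1.64. Of 47 type I interferon-stimulated genes, 46 rose and 1 did not pass (46 adjusted over the list alone, camera adjusted p = 3.34e-76 and, with an estimated correlation, 0.0451). Clock genes fell in 11 of 17 cases and rose in 1, and 5 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.000288, adjusted p = 0.123 with an estimated correlation). Mitochondrial respiration genes fell in 15 of 24 cases and 9 did not pass (19 adjusted over the list alone, camera adjusted p = 1.52e-08, adjusted p = 0.383 with an estimated correlation), in groups in which Myl2 measured 10.56 and 10.43 in 1.5 h replicates 1 and 2 and 6.88 or less at 6 h. In all 2646 genes changed, 1090 higher and 1556 lower. Of 41 lists 22 were called by camera (5 with an estimated correlation, 19 by fry), against up to 25 in other splits of these samples. The count was 1572 and 1141 without 1.5 h replicates 1 and 2, 949 without 6 h replicate 2, 1432 without the 2 libraries high in Glycam1 and 873 with the glandular score in the model. Higher calls made up 41.2%, and 16.5% with arrays centred on their medians or 55% after cyclic loess. Centring moved the median of all genes from -0.034 to -0.168 in this comparison, and from 0.022 to 0.123 at 1.5 h against untreated skin. Quantile normalization moved it here to -0.108.

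From 6 h to 24 h several cytotoxic cell genes rose further and many antiviral genes fell back. Gzmb and Gzma rose 6.93- and 6.17-fold, the inhibitory myeloid receptor genes Clec12a and Lair1 5.97- and 4.6-fold, and Ubd, a ubiquitin-like modifier, 4.14-fold. The collagenase gene Mmp13 fell by 3.13 on the log2 scale, Cmpk2 by 2.56, Ch25h by 2.49, Mx1 by 2.43 and Mx2 by 2.27. The call of Ubd was lost without 6 h replicate 2 or 3 or 24 h replicate 3 (adjusted p = 0.105, 0.0739 and 0.107). Of the 47 interferon-stimulated genes 21 fell and 1 rose, and 25 did not pass (31 and 3 adjusted over the list alone, camera adjusted p = 5.85e-24, adjusted p = 0.507 with an estimated correlation). T and natural killer cell markers rose in 7 of 23 cases and 16 did not pass (9 adjusted over the list alone, camera adjusted p = 3.23e-05, adjusted p = 0.513 with an estimated correlation), and cell division genes rose in 7 of 23 and 16 did not pass (9 adjusted over the list alone, camera adjusted p = 1.02e-06, adjusted p = 0.507 with an estimated correlation). In all 685 genes changed, 404 higher and 281 lower. The count was 142 and 304 without 6 h replicates 2 and 3, 372 and 188 without 24 h replicates 1 and 3 and 185 with the glandular score in the model. Camera called 22 lists (14 without 24 h replicate 1), against 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 7 with fry. Other splits of these samples gave up to 19 lists by camera. Higher calls made up 59%, and 80.2% with arrays centred on their medians or 44% after cyclic loess. Centring moved the median of all genes from 0.016 to 0.107.

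From 1.5 h to 24 h Saa3 rose 39-fold, Gzmb 26.3-fold, Fcgr4 17.1-fold, Ms4a4c 16.7-fold and Cxcl9 14.3-fold. Ifnb1 fell by 3.37 on the log2 scale (adjusted p = 6.18e-08), Ifna4 by 1.99, the immediate early gene Fosb by 1.7, the cornified envelope gene Sprr4 by 1.45 and Lgi1 by 1.33. The calls of Sprr4 and Lgi1 were lost without each of 5 and 3 libraries (highest adjusted p = 0.117 without 24 h replicate 2, and 0.131 without 1.5 h replicate 2). All 16 MHC class I genes rose (16 adjusted over the list alone, camera adjusted p = 1.56e-32 and, with an estimated correlation, 0.016), and acute phase and complement genes rose in 7 of 16 cases and 9 did not pass (9 adjusted over the list alone, camera adjusted p = 5.43e-10 and, with an estimated correlation, 0.0471). Immediate early genes fell in 5 of 27 cases and 22 did not pass (9 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.32e-07, adjusted p = 0.212 with an estimated correlation). In all 580 genes changed, 447 higher and 133 lower, with 321 without 1.5 h replicate 2 and 346 without 24 h replicate 2. Camera called 25 of 41 lists, 5 of them with an estimated correlation, and fry called 18. Other splits of these samples gave up to 24 lists by camera.

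Of the genes changed at 6 h and at 24 h, 379 changed in the same direction, 327 higher and 52 lower, where independent lists would share 17.2 and 4.4. The overlaps of 1.5 h with 6 h and with 24 h were 104 and 96 genes, and 36 genes were higher and 18 lower at all 3 times. In 50 simulations with all groups unchanged, the untreated one simulated as well, the mean overlap was 0. With nothing changed almost no gene is called, so that count was bound to be 0. It cannot show how much the shared untreated samples add to the overlaps. Across genes, which are not independent replicates, log2 changes at 6 h and 24 h had a covariance of 0.106 against 0.012 simulated (r = 0.73 against 0.5). Those of 1.5 h with 6 h had a covariance of 0.041 and r = 0.35, below the simulated r of 0.5. Those of 1.5 h with 24 h had 0.058 and r = 0.55. All 3 comparisons share the untreated samples, too few to be divided, and part of the excess may come from them.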

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

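Of the tests in this part, those of the treatment and of clock time, interferon proportion and hair growth were chosen only after the result was seen, as was the choice of the 4 single genes.

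Between 6 h and 1.5 h, 5 lists differed in a direct test with an estimated correlation, each at adjusted p = 0.0451. These were type I interferon-stimulated genes (median difference 2.57 log2), interferon-inducible GTPases and gamma-interferon targets (2.47), MHC class I presentation (0.81), costimulation (0.26) and lytic cell death (0.66). Between 24 h and 1.5 h the same test gave adjusted p = 0.0176 for interferon-stimulated genes (1.9), 0.016 for GTPases (2.31), MHC class I presentation (1.04) and lytic cell death (0.64), and 0.0471 for acute phase and complement genes (0.58). All were higher at the later time.

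Mmp13, Mir143, Fmnl2 and Rufy3 were lower at 1.5 h and higher at 6 h than in untreated skin, and were chosen for that, so that a direct comparison of the times was all but bound to call them and adds no support. Mmp13, a collagenase of wound edges, differed by 3.72 log2 units (adjusted p = 7.18e-07) between group means of 4.55 at 1.5 h and 8.27 at 6 h. The microRNA gene Mir143 differed by 1.35 (adjusted p = 3.96e-05), Fmnl2, an actin regulator, by 1.26 (adjusted p = 1.33e-05) and Rufy3 by 0.96 (adjusted p = 5.78e-05).

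Genes of glandular epithelium were higher in most treated biopsies than in untreated ones. In limma Krt19 was called at 1.5 h (adjusted p = 0.0411), and Krt18, Csn3 and Wfdc18 were not (0.0539, 0.0578 and 0.172). None of these was called at 6 h or 24 h. A response shared by all treated biopsies is argued against, because 2 of the 9 treated libraries, 6 h replicates 2 and 3, had a mean of Krt18, Krt19, Csn3 and Wfdc18 at or below the highest untreated value of 5.66, while 6 h replicate 1 reached 8.63 (Krt18 alone 9.14). Glandular tissue such as mammary duct in the biopsy may account for the pattern. A set of 7 duct genes, seen before the test, held Krt18, Krt19, Csn3 and Wfdc18 with Wfdc2, Cited1 and Elf5. Elf5 was called at 1.5 h (limma adjusted p = 0.0397), and Wfdc2 and Cited1 were not (0.102 and 0.146). Within groups, 13 further duct genes, listed before their values were looked at, followed the mean of these 7 across libraries. Their median r was 0.36, against a 95th percentile of 0.26 for 10000 random sets. Those sets were single genes drawn independently and matched on level. Other genes that vary together could also pass, so the r does not single out duct tissue. Of these 13 genes, 9 also had an untreated mean above the overall median, and 0 were in another list. Krt8, 1 of the 13, was called at 1.5 h and 24 h (limma adjusted p = 0.0133 and 0.0146), and the others were not called. The mean of the 7 genes spread most at 6 h, with 8.34 in replicate 1 and 5.31 and 5.21 in replicates 2 and 3. Both 6 h replicate 1 and 1.5 h replicate 1 (8.46) were also the libraries high in Glycam1, so this r alone cannot tell duct from lymph node tissue. The body site of the biopsies was not among the labels, and a response limited to some biopsies stays open.

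Of 17 clock genes 8 were lower and 2 higher at 6 h than in untreated skin. A response in proportion to the interferon response is argued against as the whole cause: the mean of 7 genes that peak with Dbp was 8.14 at 1.5 h and 8.07 at 24 h, a change of -0.07 where the ratio to the interferon-stimulated genes at 6 h predicts -0.79, so that observed and predicted differ by 0.72 (95% interval 0.44 to 1.05). A different clock time of collection may account for the pattern at 6 h, since it needs genes of the opposite phase to rise. A response that lowered clock repressors such as Nr1d1 could raise them too, so their rise cannot tell the 2 apart. At 6 h 4 genes that peak with Bmal1 had a median change of 0.51, of which 2 rose and 2 did not pass, when the 7 had a median of -1.08. Nfil3, 1 of the 2, was also higher at 1.5 h and 24 h. Its call at 24 h was lost without each of 8 libraries (highest adjusted p = 0.169, without 24 h replicate 3). At 1.5 h and 24 h the 7 were lower as well (medians -0.45 and -0.47, with 3 and 2 called), while the 4 had medians of 0.06 and -0.04. A median rise of that size beside a fall of the 7 was thus seen at 6 h alone, though 2 of the 4 did not pass there. Nfil3 was called at all 3 times, so only the other called gene rose at 6 h alone. All 7 and all 4 are members of the clock list with untreated means above the overall median. A response with another time course was not tested and stays open, and the clock times of injection and collection are not given in the sources used here, so whether they differed between the groups is not known.

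Camera called the list of 30 hair follicle genes lower than in untreated skin at 1.5 h, 6 h and 24 h, though 1, 2 and 0 genes passed and with an estimated correlation the list was not called (adjusted p = 0.497, 0.623 and 0.384). A fall that grows with time is argued against, because the mean over libraries of the median of the list was -0.64 at 24 h and -0.76 at 1.5 h, a difference of 0.12 (95% interval -0.05 to 0.3), and the median difference over genes was 0.01 (camera adjusted p = 0.959). Follicles in growth in 1 untreated biopsy, replicate 2, where Krt25 measured 10.74, cannot be told apart from a lower level in all treated biopsies: the 9 treated libraries differed from the other 2 untreated ones by -0.16 in the median of the list (95% interval -0.36 to 0.04) and by -0.33 in its mean (-0.65 to -0.02), against -0.67 and -0.97 from all 3. Without that library Krt25 and Krt71 kept their calls at 6 h with changes of -2.23 and -1.99 (adjusted p = 0.0228 and 0.0216), and camera at the preset correlation called the list at 1.5 h and 24 h (adjusted p = 0.00171 and 0.00653) but not at 6 h (adjusted p = 0.116).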

How the results depend on the processing

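The fits without the libraries high in Glycam1 and with the glandular score were chosen only after the results were seen. Over all alternatives, counts of changed genes stayed within 1.5 times in 152 cases and did not in 57, the overlap of 6 h and 24 h in 18 and 2, the overlaps with 1.5 h in 24 and 16, and counts of higher or of lower genes in 245 and 115. Named genes kept direction and side of the threshold in 9012 cases, lost their call in 429 and gained one in 148. Gene lists did so in 4715, 314 and 136 cases, and 1 list reversed: B and plasma cell markers at 1.5 h, lower with the glandular score as a covariate (adjusted p = 0.0056). Where no cause follows from an alternative's construction (a stricter threshold, fewer samples or genes, fewer degrees of freedom), the cause was not tested. Signal over background could not be judged, since no detection calls were used here.

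Counts of changed genes that moved were as follows. An adjusted p under 0.01 left 65 genes at 1.5 h, 540 at 6 h and 361 at 24 h, 767 from 1.5 h to 6 h, 149 from 6 h to 24 h, 309 from 1.5 h to 24 h and 733 at any time, with an overlap of 6 h and 24 h of 240. A fold of at least 2 left 112, 325, 292, 395, 135, 232 and 493 in that order, with an overlap of 194. Without moderation of the variance the counts were 41 at 1.5 h, 424 at 24 h, 1543, 239 and 340 between times and 1098 at any time. The floor at the 25th percentile gave 170 at 1.5 h and 436 from 6 h to 24 h, array weights 696 at 1.5 h, genes above the overall median on at least 3 arrays 1061 from 6 h to 24 h, and a fit of only the 2 groups compared 247 there. Arrays centred on their medians gave 4609 from 1.5 h to 6 h and 1133 from 6 h to 24 h. Without the libraries high in Glycam1 there were 198 at 1.5 h and 1432 from 1.5 h to 6 h. With the glandular score, which was higher in every 1.5 h and 24 h library than in untreated skin, there were 55 at 1.5 h, 307 at 24 h, 873 from 1.5 h to 6 h, 185 from 6 h to 24 h and 1451 at any time.

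Leaving out each library in turn gave 97 to 597 genes at 1.5 h, 712 to 1364 at 6 h, 423 to 756 at 24 h, 949 to 2951 from 1.5 h to 6 h, 142 to 877 from 6 h to 24 h, 321 to 653 from 1.5 h to 24 h and 1189 to 2409 at any time, and 14 to 25 lists from 6 h to 24 h. Camera with an estimated correlation called 1, 12 and 8 lists at 1.5 h, 6 h and 24 h and 5, 0 and 5 between times, in place of 22, 23, 25, 22, 22 and 25. Fry called 5 at 1.5 h, 16 at 24 h and 7 from 6 h to 24 h. With arrays centred on their medians no list called against untreated skin lost its call, but 2 did from 1.5 h to 6 h and 2 from 6 h to 24 h. The lists were not tested after quantile normalization or cyclic loess.

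With the replicate number as a replicate block the counts were 442, 1136 and 670 at the 3 times, 2630, 616 and 593 between times and 2202 at any time, with an overlap of 368, all within 1.5 times. Of 18 pairs of samples with the same number, 4 had deviations correlated above 0.1 (r = -0.22 to 0.33), and 6 of 12 samples were closest to their own number. The median r was 0.04 for equal numbers and 0.01 for others. No clear pairing was seen, and a shared batch or day cannot be excluded.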

Other observations

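The test of natural killer against T cell genes and the splits of the samples were chosen before their results were seen, and the slow muscle and lymph node genes were listed only after the libraries had been looked at.

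Some barrier and skin-resident genes were lower at 24 h. Of 20 differentiated keratinocyte markers 3 fell and 17 did not pass (12 fell adjusted over the list alone, camera adjusted p = 2.8e-10, adjusted p = 0.13 with an estimated correlation), led by Hrnr, and 0 of 13 basal keratinocyte markers passed in limma (5 at an unadjusted p under 0.05, camera adjusted p = 0.000915, adjusted p = 0.335 with an estimated correlation). Dct, a pigment enzyme, fell by 1.04 among 8 melanocyte markers, of which 2 fell and 6 did not pass (camera adjusted p = 0.00108, adjusted p = 0.268 with an estimated correlation). The call of Dct was lost without untreated replicate 2 or 3 or 24 h replicate 3 (adjusted p = 0.0756, 0.0785 and 0.0769). Fap, a protease of activated fibroblasts, fell by 0.96 and was the member called among 23 fibroblast and matrix genes (camera adjusted p = 0.0252, adjusted p = 0.72 with an estimated correlation, and 0.965 without 24 h replicate 3 or 0.178 without untreated replicate 3). Among 20 cholesterol and fatty acid synthesis genes Ch25h rose 4.89-fold and Elovl6 fell by 0.74 (camera adjusted p = 0.0147, adjusted p = 0.293 with an estimated correlation, and 0.0564 without 24 h replicate 1).

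At 1.5 h Hsph1, a heat shock protein, fell by 0.76 (adjusted p = 0.0625 without untreated replicate 3) among 15 heat shock and unfolded protein response genes (camera adjusted p = 0.0201, adjusted p = 0.497 with an estimated correlation, and 0.0514 or 0.0859 without untreated replicate 1 or 3). Socs3, a brake on cytokine receptors, rose 1.88-fold, a call lost without each of 9 libraries (highest adjusted p = 0.148, without 1.5 h replicate 2). At 6 h Mt2 rose 2.5-fold, and Casp14, a protease of cornifying keratinocytes, fell by 0.8 (adjusted p = 0.0558 without 6 h replicate 2 and 0.05 without untreated replicate 2). Mean levels of 6 slow muscle genes were 9.23 and 9.28 in 1.5 h replicates 1 and 2 and 9.57 and 8.18 in 24 h replicates 1 and 3, against 5.07 to 6.4 in the other libraries. Of 12 B cell and lymph node genes, the median r with Glycam1 within groups was 0.95.

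A hypothesis is that the granzyme genes of 24 h came with natural killer cells more than with T cells. The median change at 24 h was 1.74 for 6 natural killer cell genes and 0.25 for 8 genes of the T cell receptor complex. That is a difference of 1.49 (exact permutation test over genes, two-sided, p = 0.00333), in the direction the idea needs. Of these, 5 of 6 and 0 of 8 genes rose in limma (0 of the 8 also at an unadjusted p under 0.05), with Ncr1, named after its value was seen, up by 1.98 log2 units. All 14 genes belong to the list of T and natural killer cell markers, genes are not independent replicates, and no cells were counted. In untreated skin the means were 4.31 to 4.5 for the 6 genes and 5.82 to 5.89 for the 8. From that higher level the same added RNA gives a smaller log2 change, so the difference does not settle which cells came.

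The real split of the samples was set against the other splits. For genes changed at any time, 1 of 100 splits gave as many genes, the real one (2274, highest other 75), which excludes chance at that share. Comparisons of 3 with 3 samples allow 10 splits, too few for a share under 0.05. The real count of genes and the highest other were 439 and 1 at 1.5 h, 1215 and 0 at 6 h, 670 and 0 at 24 h, 2646 and 0 from 1.5 h to 6 h, 685 and 0 from 6 h to 24 h and 580 and 38 from 1.5 h to 24 h. For lists they were 22 and 20, 23 and 24, 25 and 21, 22 and 25, 22 and 19, and 25 and 24 in the same order, and 3 splits gave as many lists at 6 h and from 1.5 h to 6 h, 1 split elsewhere. The number of lists that camera called at the preset correlation thus differed little between the real and other splits. By itself it is no evidence of a change.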
